A study of Homo sapiens with 6 samples.

How the data were processed

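Total RNA of SiHa cells treated with 20 µM cisplatin for 48 h was read as single-end reads of 50 bases on the DNBSEQ platform, with 6 libraries, 3 from shcontrol and 3 from shVPS13C cells, per the labels. The build, hg38, comes from the submitters' processing notes; the aligner, the counting tool, the annotation and any use of strand are not given in the sources used here. The gene and transcript tables hold read counts per the file headers, and these are estimated counts that the authors derived per gene and per RefSeq transcript. They are not scaled, and 14.7% to 15.6% of values per library had a decimal part other than exactly 0. The authors' FPKM values (fragments per kilobase of transcript, scaled to the library's reads) stand beside them in the gene table. A further set of deposited columns is the authors' normalized read count, a signal made by scaling the counts of each library by 1 factor. The counts were multiplied by that factor, which ran from 0.958 to 0.996 over the libraries. In genes with more than 100 counts, 100% of ratios of normalized counts to counts lay within 1% of the factor. The counts were the input of the main test, and FPKM served 1 alternative. Another 24 per-sample columns, counted over the 6 libraries together, and 16 columns of means were not used, because they repeat the same libraries on other scales.

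The gene table lists 17156 genes, of which 681 had 0 counts in all libraries, and the library totals lay between 15643965 and 16333424. Summed transcript counts and gene counts differed by at most 0.06 over 17155 genes in both tables. Counts were rounded to whole numbers, filtered with edgeR filterByExpr by group, which left 12671 genes, and scaled by TMM factors of 0.996 to 1.01. The 2 groups were compared with the edgeR quasi-likelihood test (glmQLFit, robust set to false, no covariate, 4 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are shVPS13C over shcontrol; SE and 95% confidence intervals come from the same fit. The common biological coefficient of variation was 0.035, and pairs of libraries of 1 group differed by 1.93 to 3.52 chi-square per degree of freedom, beyond counting error. Groups did not overlap in 23.1% of tested genes, where chance gives 10%, and in 564 of the 570 called genes. For VPS13C and GSTP1 an exact two-sided permutation test of log2 CPM was added. CPM values are edgeR's cpm on the TMM-scaled library size. Coordinates were read from a RefSeq gene annotation through the Entrez numbers, with a match for 12610 tested genes. GENCODE release 29 on GRCh38 gave transcript lengths, GC content, 3' UTRs, 50-base stretches and exon overlaps.

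Gene lists, 39 in all, were written with the tests, the named-gene rule and the alternatives before the data were examined. The 33 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists: 9 passed, 6 up and 3 down. With an estimated correlation 0 passed and 5 had an unadjusted p under 0.05. fry, which tests whether members move on balance one way, passed 5, and its mixed test, whether members change in either direction, passed 28; neither compares a list with other genes. The lists share members: SLC7A11 is in those of ATF4, NRF2 and glutathione synthesis, CHAC1 in those of ATF4 and glutathione synthesis, GCLM in those of NRF2 and glutathione synthesis, BIRC3 in those of NF-kB and anti-apoptotic genes, and GDF15 in those of p53 targets and senescence-associated secretion.

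Named genes were VPS13C and GSTP1. They were also the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap, with LOC, antisense and pseudogene entries passed over. From each list past camera they were the 3 members with the smallest p, and from each other list with a called member the 1 with the smallest p. Other genes that the text names were chosen after their values were seen. Of the named genes, 13 have over 5% of their 50-base stretches in another gene, from 5.92% in GBP4 to 97.1% in H2AC19, with CCNE2 at 35.2%, RRM2 at 20.3%, GJA5 at 17.0%, RPLP0 at 12.3% and NR4A1 at 10.1%. Over 5% of exon bases lie on the same strand as another gene in 3 of them and opposite another gene in 7.

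The steps were tested on simulated data of the same size. With 12611 genes in the step and changes planted in 200 genes, the gene test recovered 55.2% at 1.2-fold, 87.9% at 1.5-fold and 95.5% at 2-fold, and 5.95% of its calls were false. With no change planted it made 1 call. The transcript step, over 36719 simulated transcripts, recovered 0, 0 and 13.3% at those folds; the 79523 transcripts deposited left 41617 after the filter, with a common biological coefficient of variation of 0.698. A simulated list of 30 genes shifted together gave a camera adjusted p of 1.53e-07, and 0.0825 with an estimated correlation, and 0 of 30 random lists passed. Genes were drawn independently of each other there. The random lists therefore cannot show how often camera passes lists whose genes vary together.

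The alternatives were RLE factors, total counts only, no filter, a filter at a mean of 1 CPM, DESeq2, limma-voom, robust quasi-likelihood, the replicate number as a block, glmTreat against 1.2-fold, limma-trend on log2(FPKM + 1) for genes with an FPKM of at least 1 in 3 libraries, and each library left out. A scan related 3' UTR 7-mers found in at least 100 genes to log2 fold changes (limited to 1 in size). It covered 3' UTRs of at least 50 bases, with 100 permutations of the genes. The covariates were 3' UTR length, 3' UTR GC content and expression. The trend on GC content and length was a loess fit with a span of 0.4, and standard errors of medians came from 1000 bootstrap resamples. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Biostrings 2.70.1, Python 3.11.15 and matplotlib 3.10.9 were used.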

Results

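SiHa cells, a human papillomavirus-positive line from a cervical squamous (epidermoid) carcinoma, were profiled by sequencing of total RNA after 48 h in 20 µM cisplatin, a platinum drug that crosslinks DNA. The labels place 3 libraries in a control group (shcontrol) and 3 in a group with VPS13C knocked down (shVPS13C). The series title ties loss of VPS13C to cisplatin resistance and to GSTP1, so the comparison asks how transcript levels differ between knockdown and control under the drug. All 6 libraries had cisplatin, so a response to the drug itself is not measured. The shcontrol libraries 1, 2 and 3 held 16319769, 15832188 and 15643965 estimated counts. The shVPS13C libraries 1, 2 and 3 held 16333424, 15761967 and 16007623. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries. On the first principal component, with 29.3% of the variance, the groups lay apart, with all shVPS13C libraries on one side.

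VPS13C, which encodes a bridge-like lipid transfer protein at contacts between the endoplasmic reticulum and late endosomes or lysosomes, stood at 51.5 ± 2.96 CPM (SD, n = 3) in shcontrol and 25.4 ± 1.96 (SD, n = 3) in shVPS13C. Its fold was 0.494, a log2 fold change of -1.02 (SE 0.065, 95% confidence interval -1.15 to -0.88, edgeR quasi-likelihood adjusted p = 4.77e-10). The gene (Entrez 54832) lies on chromosome 15, 61852389 to 62060447 on hg38. GSTP1, a glutathione S-transferase that conjugates electrophiles to glutathione (Entrez 2950, chromosome 11, 67583812 to 67586653), stood at 377 ± 12.3 CPM in shcontrol and 392 ± 13.7 in shVPS13C (SD, n = 3). Its log2 fold change was 0.06 (SE 0.040, 95% confidence interval -0.03 to 0.14, edgeR adjusted p = 0.47). The groups overlapped, and a rise in transcript level beyond 0.14 lay outside the interval. GSTP1 protein, its activity and cells without the drug were not measured in these libraries. The exact two-sided permutation test of log2 CPM gave p = 0.1 for VPS13C, the smallest p that 3 against 3 allows, and p = 0.2 for GSTP1.

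**Figure D1:**
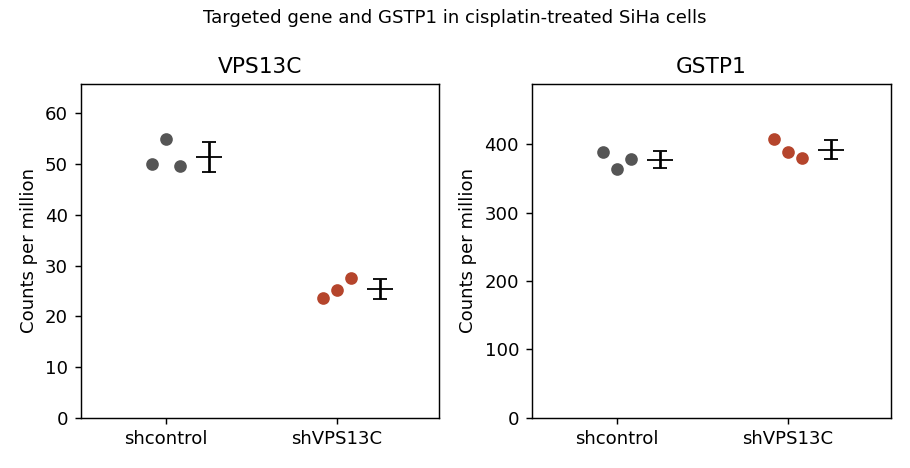
CPM of VPS13C (left) and GSTP1 (right) in each library of the shcontrol and shVPS13C groups; points are libraries, the bar beside them the mean ± SD of 3, and both axes start at 0. Every shVPS13C library lies below every shcontrol library for VPS13C (means 25.4 and 51.5), while the groups overlap for GSTP1 (392 and 377).

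Of the 12671 genes tested, 570 (4.50%) differed at an adjusted p under 0.05 by the edgeR quasi-likelihood test: 288 were higher and 282 lower in shVPS13C. DESeq2 called 323 (163 higher, 160 lower) and limma-trend on log2(FPKM + 1) called 150 (63 higher, 87 lower). Most differences were small, with a median of 0.24 on the log2 scale for the higher genes and -0.23 for the lower ones. The size reached 1.5-fold in 47 genes (36 higher, 11 lower) and 2-fold in 16 (11 higher, 5 lower). The largest rise among genes with a mean of at least 5 CPM was in DAB2, an endocytic adaptor and tumour suppressor, from 8.95 ± 1.10 to 17.3 ± 1.32 CPM (SD, n = 3; log2 0.95, adjusted p = 1.68e-06). Next came the extracellular proteoglycan gene SPOCK1 (0.70, adjusted p = 0.0017), the connexin gene GJA5 (0.69) and the guanylate cyclase subunit gene GUCY1A2 (0.67). They were followed by the corepressor gene TLE2 (0.62), the kinase gene SBK1 (0.60), the endocytic receptor gene LRP2 (0.59) and HOOK1 (0.58), which links cargo to microtubules. Above the same level, the largest falls after VPS13C and a histone gene were in IMPA2, an inositol monophosphatase gene, from 71.6 ± 3.10 to 44.2 ± 3.34 CPM (log2 -0.69, adjusted p = 2.01e-08). TNIP1, an inhibitor of NF-kB signalling, fell from 91.8 ± 0.857 to 57.8 ± 2.15 CPM (-0.67, adjusted p = 1.14e-09). The connexin gene GJB5 (-0.60), the glycine transporter gene SLC6A9 (-0.59), G0S2 (-0.56), an inhibitor of lipolysis, and the collagen gene COL11A2 (-0.52, adjusted p = 0.0437) also fell. The replication-dependent histone gene H2AC19 had the most negative value of the called genes (log2 -2.64, SE 0.505, adjusted p = 0.00306; 28.0 ± 13.8 to 4.43 ± 7.68 CPM). Only shVPS13C replicate 1 had counts of it in that group, so without it no fold can be given. Its call ended with DESeq2 (adjusted p = 0.803), robust quasi-likelihood (0.353), glmTreat (0.0607) and limma-trend (0.0896), over a range of 3.22e-23 to 0.803, and 97.1% of its 50-base stretches are also in H2AC18. Against a null of 1.2-fold (edgeR glmTreat), 6 genes passed: DAB2 and CEMIP were higher, and VPS13C, IMPA2, TNIP1 and G0S2 were lower. CEMIP, a hyaluronan-degrading protein's gene, is named here after its value was seen. The 7-mer AATCCAA, picked in these data for its link to lower values, was in the 3' UTR of 30.8% of the lower genes searched, IMPA2 and TNIP1 among them, 9.72% of the higher ones and 11.3% of those not called. Without shVPS13C replicate 1, 2 or 3 the count of changed genes was 204, 273 and 274. In the same order there were 101, 123 and 139 higher, 103, 150 and 135 lower, and 6, 9 and 12 past 2-fold. Without shcontrol replicate 2, 174 genes were higher and 10 passed 2-fold. The call of TLE2 ended without shVPS13C 3 (adjusted p = 0.0511) and that of HOOK1 without shVPS13C 2 (0.0654). LRP2 lost its call without shcontrol 1 or 2 or shVPS13C 1 or 3 (adjusted p up to 0.1), and COL11A2 without any library but shcontrol 1 (up to 0.167). DESeq2 also ended the calls of HOOK1 (adjusted p = 0.091), LRP2 (0.0989) and COL11A2 (0.202). With limma-trend on log2(FPKM + 1), HOOK1 stood at 0.24 (adjusted p = 0.236) and COL11A2 at -0.14 (0.626).

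Genes of amino acid shortage and endoplasmic reticulum stress under ATF4, the transcription factor of the integrated stress response, were lower in shVPS13C: of 28 tested members, 9 fell, 1 rose and 18 did not pass (1 rose and 11 fell adjusted over the list alone). TRIB3, a pseudokinase gene, fell from 33.4 ± 1.86 to 23.5 ± 0.323 CPM (SD, n = 3; log2 -0.51, adjusted p = 5.89e-05). SLC7A11, the cystine importer gene, fell from 29.5 ± 0.888 to 21.1 ± 0.571 CPM (-0.49, adjusted p = 1.00e-04) and XPOT, a tRNA export gene, by 0.26. The other members that fell, listed after their values were seen, were CHAC1 (-0.52), NUPR1 (-0.36), the asparagine synthetase gene ASNS (-0.34), DDIT3 (-0.30), STC2 (-0.25) and PPP1R15A (-0.14), and the member that rose was DDIT4 (0.17). The list's median was -0.10 (camera adjusted p = 1.42e-08; adjusted p = 0.119 with an estimated correlation). Genes of NF-kB and inflammatory cytokines were lower too, with 7 of 23 tested members down, 16 not past the test and 10 down adjusted over the list alone. Among them the collagenase gene MMP1 fell by 0.39, the stromelysin gene MMP3 by 0.41 and BIRC3, an inhibitor of apoptosis, by 0.31 on the log2 scale. RELB (-0.35), IL32 (-0.31), LIF (-0.21) and NFKB2 (-0.16) also fell, and the list's median was -0.14 (camera adjusted p = 5.06e-06; adjusted p = 0.119 with an estimated correlation). In the list of p53 targets 4 of 28 tested members fell and 24 did not pass (1 rose and 5 fell adjusted over the list alone). They were GADD45A (115 ± 4.70 to 85.4 ± 1.57 CPM, log2 -0.43, adjusted p = 1.70e-06), which acts in growth arrest, GDF15 (-0.41), a secreted stress cytokine, BTG2 (-0.27), which restrains proliferation, and the ribonucleotide reductase gene RRM2B (-0.24). The median over all 28 was -0.01 (camera adjusted p = 0.0199; adjusted p = 0.289 with an estimated correlation). The 7-mer AATCCAA was in the 3' UTRs of 3 of the 28 ATF4 list members, TRIB3 among them (median -0.25 with it, -0.051 without). It was in 2 of the 23 NF-kB list members (-0.28 with it, -0.14 without) and 6 of the 28 p53 targets, BTG2 among them (-0.11 with it, -0.0074 without). Another split of the 6 libraries into 3 and 3 gave 7 lists past camera, where the real one gave 9. Without shcontrol 1 or shVPS13C 1 the p53 list lost its call (adjusted p = 0.0924 and 0.0543), and without shcontrol 3 its median was -0.04. Calls ended without single libraries for DDIT4 (any but shcontrol 3, adjusted p up to 0.202), PPP1R15A (shcontrol 1 or 2, shVPS13C 1 or 3, up to 0.143) and RELB (shVPS13C 3, 0.0731). They ended too for IL32 (shVPS13C 1, 0.0506), LIF (shcontrol 3, shVPS13C 1 or 3, up to 0.111), NFKB2 (any but shcontrol 1, up to 0.0946) and RRM2B (shcontrol 2, shVPS13C 1 or 2, up to 0.105).

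**Figure D2:**
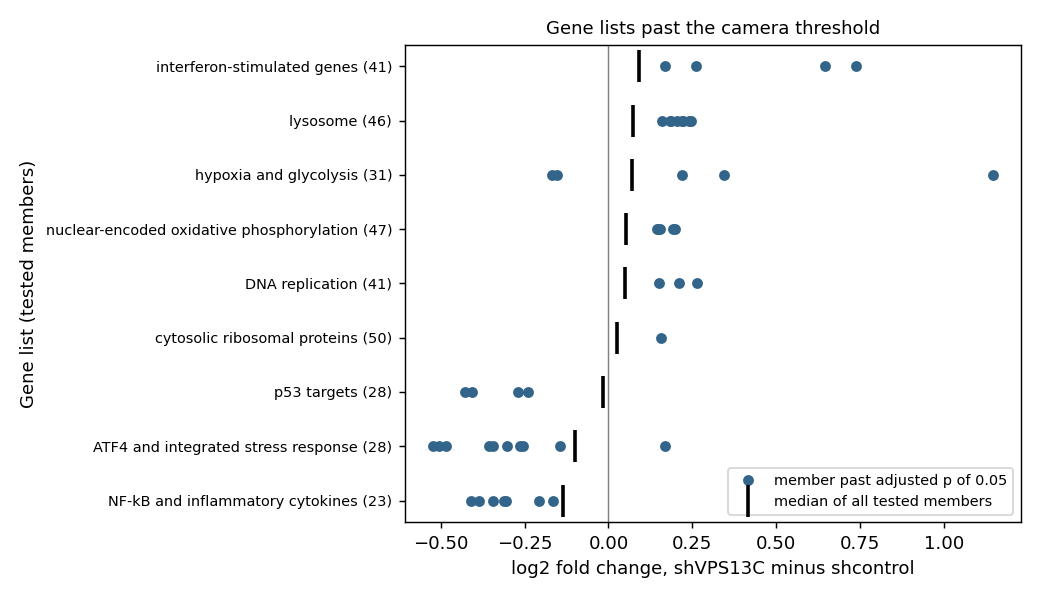
Gene lists past the camera threshold, with the number of tested members in brackets; the x axis is the log2 fold change of shVPS13C over shcontrol, dots are members past an adjusted p of 0.05 and the vertical bars the median of all tested members. The medians run from -0.14 for NF-kB and inflammatory cytokines to 0.09 for interferon-stimulated genes.

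Lysosomal genes were higher in shVPS13C, with 8 of 46 tested members up, 38 not past the test and 11 up adjusted over the list alone. NPC2, which acts in cholesterol export from the lysosome, rose from 140 ± 2.06 to 163 ± 2.06 CPM (SD, n = 3, log2 0.22, edgeR adjusted p = 0.00164). The cathepsin genes CTSH and CTSC rose by 0.25 and 0.22. CTSF (0.24), the proton pump gene ATP6V1A (0.20), GLB1 (0.19), NEU1 (0.18) and GRN (0.16) also rose, and the list's median was 0.07 (camera adjusted p = 7.09e-06; adjusted p = 0.377 with an estimated correlation). With fry in one direction the lysosomal list did not pass (adjusted p = 0.0624). Of 41 interferon-stimulated genes tested, 4 rose and 37 did not pass (9 rose and 1 fell adjusted over the list alone). They were the guanylate-binding protein genes GBP1 (0.26, adjusted p = 0.00482) and GBP4 (0.74; 2.62 ± 0.211 to 4.36 ± 0.710 CPM), CMPK2 (0.65) and the ubiquitin-like modifier ISG15 (0.17). The median was 0.09 (camera adjusted p = 9.28e-04; adjusted p = 0.119 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation rose in 5 of 47 tested members, with 42 not past the test and 9 up adjusted over the list alone: the ATP synthase genes ATP5F1A (0.20) and ATP5F1B (0.15), NDUFV1 (0.19), SDHA (0.15) and UQCRC2 (0.14). Their median was 0.05 (camera adjusted p = 6.58e-04; adjusted p = 0.434 with an estimated correlation). In the list of hypoxia and glycolysis 3 of 31 tested members rose and 2 fell (6 and 2 adjusted over the list alone). The risers were the neuronal enolase gene ENO2 (0.34), the collagen hydroxylase gene P4HA2 (0.22) and the carbonic anhydrase gene CA9 (1.15, at 0.797 ± 0.148 CPM in shcontrol), while the glycolytic genes HK1 (-0.17) and LDHA (-0.15) fell. The median was 0.07 (camera adjusted p = 0.00211; adjusted p = 0.317 with an estimated correlation). Of 41 DNA replication genes tested, 3 rose (3 adjusted over the list alone): the G1/S cyclin genes CCNE1 (0.21) and CCNE2 (0.26) and RRM2 (0.15), with a median of 0.05 (camera adjusted p = 0.00562; adjusted p = 0.434 with an estimated correlation). Of 50 cytosolic ribosomal protein genes tested, 1 rose (1 adjusted over the list alone), RPS14 (0.16, adjusted p = 0.0249). RPLP0 (0.14, adjusted p = 0.0593) did not pass. The list's median was 0.03 (camera adjusted p = 0.00562; adjusted p = 0.611 with an estimated correlation). Without shcontrol 2 or shVPS13C 1 or 2 the ribosomal list lost its call (adjusted p = 0.202, 0.0543 and 0.0865), and its median lay between 0.02 and 0.05 over the 6 libraries left out in turn. With fry in one direction the lists of oxidative phosphorylation (adjusted p = 0.0817), DNA replication (0.0817) and ribosomal proteins (0.324) did not pass either. The single calls of NPC2, CTSH, CTSC, GBP1, ATP5F1A and ENO2 held without any 1 library. Those of CTSF (shcontrol 2 or 3, shVPS13C 1 or 2, adjusted p up to 0.149), GLB1 (shcontrol 2, shVPS13C 1 or 3, 0.165), NEU1 (shVPS13C 1 or 3, 0.0997), GRN (shcontrol 2, shVPS13C 1 or 2, 0.135) and ATP6V1A (shVPS13C 1, 0.0582) ended without the libraries named. So did those of GBP4 (shVPS13C 1 or 3, 0.0919), CMPK2 (any but shcontrol 1, 0.233), ISG15 (any but shVPS13C 3, 0.185), NDUFV1 (shVPS13C 1 or 2, 0.107), ATP5F1B (any shVPS13C, 0.0778), SDHA (shVPS13C 1 or 3, 0.114) and UQCRC2 (any but shcontrol 1, 0.169). The same held for CA9 (shcontrol 1 or 2, shVPS13C 1 or 3, 0.111), P4HA2 (shcontrol 1, shVPS13C 1, 0.103), HK1 (shVPS13C 1, 0.0737) and LDHA (any but shcontrol 2, 0.113). It held too for CCNE1 (shVPS13C 1 or 2, 0.107), CCNE2 (shcontrol 3, shVPS13C 2 or 3, 0.134; log2 0.17), RRM2 (shcontrol 2 or 3, shVPS13C 1 or 3, 0.157) and RPS14 (shcontrol 2 or 3, shVPS13C 1 or 2, 0.128).

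Genes around glutathione and cisplatin handling moved in few cases. Of 11 glutathione S-transferase genes tested, 1 rose, GSTM3 (0.20, adjusted p = 0.0327), and the list missed the threshold (camera adjusted p = 0.0534; adjusted p = 0.48 with an estimated correlation). Its median was 0.06, with 10 of 11 members above 0. It passed, upward, with no filter (adjusted p = 0.0314) and without shcontrol 1 (0.0325), shcontrol 3 (0.0245), shVPS13C 2 (0.0434) or shVPS13C 3 (0.0408), over a range of 0.0245 to 0.48. Of 19 genes of glutathione synthesis and peroxidases, SLC7A11, GCLM (-0.26), the modifier subunit of the first enzyme of glutathione synthesis, and CHAC1, which breaks glutathione down, fell, and the peroxidase gene GPX1 rose (0.15). Of 30 NRF2 targets tested, SLC7A11, GCLM and AKR1C3 (-0.25) fell and PRDX1 (0.14) rose. Of 16 platinum transporters tested, 1 rose, LRRC8A (0.17), a subunit of volume-regulated anion channels. No member passed among 27 genes of nucleotide excision repair and 30 of the Fanconi anaemia and homologous recombination pathways, while 1 of 30 pro-apoptotic genes rose and 1 of 11 anti-apoptotic genes, BIRC3, fell. Calls ended without single libraries for GSTM3 (shcontrol 2, any shVPS13C, adjusted p up to 0.182), GPX1 (any but shcontrol 3, 0.149) and AKR1C3 (any but shcontrol 2, 0.0833). They ended too for PRDX1 (shcontrol 1 or 3, shVPS13C 1 or 3, 0.169) and LRRC8A (shcontrol 2, shVPS13C 2 or 3, 0.0963).

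Among genes of epithelial identity and adhesion, some rose and others fell. E-cadherin's gene CDH1 rose (0.27, adjusted p = 0.00359), while 3 fell, the desmosomal genes DSG2 (-0.25) and PKP2 (-0.34) among them, of 20 junction genes tested. The laminin chain gene LAMB3 fell from 432 ± 23.7 to 354 ± 9.42 CPM (SD, n = 3; log2 -0.29, adjusted p = 1.83e-04) and the integrin gene ITGB4 rose (0.29), among 13 basal keratinocyte genes. SLPI, a secreted protease inhibitor, rose from 324 ± 13.6 to 392 ± 5.93 CPM (0.28, adjusted p = 1.52e-04), the 1 member past the test of 11 epidermal differentiation genes. Of 27 genes of epithelial-mesenchymal transition, COL5A1 (0.42), TNC (0.25) and PLAUR (0.21) rose and 2 fell, the receptor kinase gene AXL (-0.23) among them. Of 24 genes of senescence-associated secretion, IGFBP7 (0.20), TIMP2 (0.18) and STC1 (0.24) rose and 2 fell, GDF15 among them. Calls ended without single libraries for PKP2 (shcontrol 1 or 3, shVPS13C 1 or 2, adjusted p up to 0.116), ITGB4 (shcontrol 2, shVPS13C 1 or 2, 0.0979) and COL5A1 (shVPS13C 2, 0.0522). They ended too for TNC (shVPS13C 3, 0.0837), PLAUR (shVPS13C 1, 0.0634), AXL (shVPS13C 1, 0.0571), IGFBP7 (any but shcontrol 3, 0.141), TIMP2 (shVPS13C 2, 0.0738) and STC1 (shVPS13C 1, 0.0743).

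Stress genes outside the ATF4 list moved both ways. Of 23 heat shock genes, the chaperone genes HSPA8 (0.23) and HSPA1A (0.15) rose, and SERPINH1, a collagen chaperone gene, fell from 392 ± 8.19 to 318 ± 14.4 CPM (SD, n = 3; log2 -0.30, adjusted p = 6.87e-05). Of 29 AP-1 and immediate early genes, NR4A1 (0.27), FOS (0.26) and FOSB (0.30) rose and FOSL1 (-0.23) and CCN1 (-0.15) fell. The groups overlapped for FOS and FOSB, and their calls ended with robust quasi-likelihood (adjusted p = 0.354 and 0.326), DESeq2 (0.411 and 0.335) and limma-trend (0.177 and 0.133). Of 24 genes of the unfolded protein response, XBP1 (-0.22) fell, and none of 17 JNK and p38 kinase genes passed. In lipid and membrane biology, ACSL4, which activates polyunsaturated fatty acids, fell (-0.26, adjusted p = 3.88e-04) and the triglyceride synthesis gene DGAT1 rose (0.19) among 22 fatty acid genes, with none of 24 cholesterol genes past the test. Of 36 autophagy genes, ATG3 (-0.16) fell, and of 10 genes of the VPS13 and bridge-like lipid transfer family, VPS13C alone passed (camera adjusted p = 0.0534 for the list; adjusted p = 0.611 with an estimated correlation). This list holds the knocked-down gene itself, so its direction is not independent of the knockdown. It passed, downward, with no filter (adjusted p = 0.0279) and without shcontrol 3 (0.0033) or shVPS13C 3 (0.0116), and its median was above 0 without shcontrol 1 or 2 or shVPS13C 1 or 2 (up to 0.02). None of 33 mitosis genes and 21 replication-dependent histone genes of the lists passed. Calls ended without single libraries for HSPA1A (shcontrol 1 or 2, shVPS13C 1 or 2, adjusted p up to 0.185), FOS (shcontrol 2 or 3, shVPS13C 1 or 2, 0.216; log2 0.17) and FOSB (the same 4 libraries as FOS, 0.115). They ended too for CCN1 (any but shcontrol 2, 0.211), XBP1 (shVPS13C 3, 0.06), DGAT1 (shcontrol 1 or 2, shVPS13C 1 or 2, 0.138) and ATG3 (any but shcontrol 1, 0.183).

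Across the lists that missed the camera threshold, from the glutathione S-transferase list to the platinum transporters, adjusted p ran from 0.0534 to 0.957. Adjusted over the list alone, the members up and down were 2 and 3 for glutathione synthesis, 1 and 1 for platinum transporters, 1 and 2 for anti-apoptotic genes, 0 and 0 for autophagy, 0 and 2 for the unfolded protein response and 4 and 2 for heat shock. They were 4 and 3 for AP-1 and 1 and 0 for JNK and p38 kinases, and 3 and 0 for epidermal differentiation, 1 and 2 for basal keratinocyte genes, 8 and 4 for epithelial-mesenchymal transition, 2 and 3 for epithelial junctions and 6 and 3 for senescence-associated secretion. For the other lists that missed the threshold, members up and down adjusted over the list alone numbered the same as over all genes tested. Beside the glutathione S-transferase and VPS13 lists, camera passed the mitosis list without shVPS13C 2 (adjusted p = 0.0217), epidermal differentiation without shcontrol 3 (0.0119) or shVPS13C 3 (0.0416) and epithelial-mesenchymal transition without shVPS13C 1 (0.0163), all upward. With all 6 libraries and an estimated correlation, adjusted p was 0.885, 0.666 and 0.562 for these lists. The median, mean and camera direction differed in sign for the histones (-0.0089, 0.021, up), the platinum transporters (0.0031, -0.020, up), cholesterol (0.033, -0.0027, up), autophagy (-0.00054, 0.0091, down) and epithelial junctions (0.018, -0.018, up).

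Markers of other cell types were few among the tested genes. Of 12 fibroblast markers 2 were tested and COL1A1 rose from 14.7 ± 0.172 to 19.9 ± 1.33 CPM (SD, n = 3; log2 0.43, adjusted p = 0.00171). Of 16 immune markers 3 were tested and CD14 rose from 24.6 ± 1.97 to 31.1 ± 1.37 CPM (0.34, adjusted p = 0.00513). None of 3 endothelial and 3 HEK293-like markers tested passed, and of 6 glandular endocervix markers WFDC2 (0.21) rose. The WFDC2 call ended without shcontrol 2 or any shVPS13C library (adjusted p up to 0.12). Of the metallothioneins 3 were tested and none passed (0 up and 1 down adjusted over the list alone), and none of the 13 mitochondrially encoded genes was in the tested set. With fewer than 5 tested members, the fibroblast, endothelial, immune, HEK293-like, metallothionein and mitochondrially encoded lists had no list test.

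At transcript level, 0 of 41617 tested transcripts passed the edgeR quasi-likelihood test, with 2050 at an unadjusted p under 0.05; no other tool was run on them. The main VPS13C transcript stood at 48.9 ± 3.19 CPM in shcontrol and 23.7 ± 1.59 in shVPS13C (SD, n = 3), with a log2 fold change of -1.04 (SE 0.081, adjusted p = 0.34), and the minor one at 2.78 ± 0.115 and 1.85 ± 0.275 (-0.58, adjusted p = 1.0). The 1 tested GSTP1 transcript had a log2 fold change of 0.06 (379 ± 12.2 to 396 ± 13.7 CPM). In data simulated at this size the transcript step recovered 13.3% of planted 2-fold changes, so a count of 0 does not show that no transcript differed. Without shcontrol 1 or without shVPS13C 3 the count was 1.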

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

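All alternatives here were chosen beforehand. VPS13C (log2 fold change -1.08 to -0.75, the last on the log2(FPKM + 1) scale) and GSTP1 (0.03 to 0.08) kept their direction and their side of the threshold in all 16 alternatives. Against 1.2-fold (glmTreat), 6 genes changed, 2 higher and 4 lower, 2 of them past 2-fold, since that test asks for a larger change. DESeq2 gave 323 genes (163 higher, 160 lower, 4 past 2-fold; 306 shared with the edgeR calls in the same direction), and limma-trend on log2(FPKM + 1) gave 150 (63 higher, 87 lower, 0 past 2-fold, 1954 at an unadjusted p under 0.05); the cause was not tested. With no filter 30 genes passed 2-fold, as 16438 were tested. Leaving out 1 library in turn, with fewer samples, gave 204 to 463 changed genes, 101 to 238 higher, 103 to 225 lower, 6 to 21 past 2-fold and 8 to 12 lists, and 0 to 1 transcripts changed or higher; without shVPS13C 1, 2 and 3 it was 204, 273 and 274 genes, and without shcontrol 2 it was 174 higher and 10 past 2-fold. The other settings gave 483 (replicate block) to 758 (no filter) genes. Deviations of libraries with the same number had correlations of 0.0403, -0.00699 and -0.15 across genes, which are not independent replicates. These values show no strong shared signal by number but cannot show that the libraries were unpaired, and the labels state no pairing. Of 113 called genes followed by name, 66 lost the call without some library and 47 kept it in all 6; the replicate block ended those of ATG3 (adjusted p = 0.0664), GPX1, HSPA1A, IGFBP7, PRDX1 and TCF7L1. Of the same 113 calls, glmTreat ended 107, limma-trend 56, DESeq2 24, robust quasi-likelihood 5 (H2AC19, FOS, FOSB, TICAM2 and TBC1D3C) and limma-voom 4 (COL11A2, ATG3, CMPK2 and TICAM2). Those that DESeq2 ended had adjusted p from 0.0558 (DGAT1) to 0.803 (H2AC19), and TLE2, LRP2, HOOK1, COL11A2, GSTM3, GBP4, ISG15, CTSF, GLB1, CMPK2, DDIT4, AKR1C3, ITGB4, PKP2 and WFDC2 were among them. For lists, 0 passed with an estimated correlation, 5 with fry in one direction and 28 with fry in either. The estimated correlation was 0.0051 for NF-kB, -0.0029 for interferon-stimulated genes and -0.0055 for p53 targets, under the preset 0.01. These values argue against members varying together as why those lists lost their call. In the other lists past camera it ran from 0.036 (hypoxia and glycolysis) to 0.22 (ribosomal proteins). The simulated list of independent genes lost its call too (camera adjusted p = 0.0825). The cause in the other lists and with fry was not tested. None of the 113 called genes followed by name reversed, and no called list did. The other called genes were not followed in direction. Among uncalled lists, a filter at a mean of 1 CPM turned the medians of the Fanconi (-0.0096), platinum (-0.00029), autophagy (0.00014) and glandular endocervix (-0.036) lists. Leaving out 1 library turned some medians near 0, with ranges of -0.0077 to 0.013 for Fanconi, -0.054 to 0.025 for the VPS13 family, -0.031 to 6.7e-05 for anti-apoptotic genes, -0.018 to 0.0094 for autophagy, -0.045 to 0.0052 for basal keratinocyte genes, -0.0092 to 0.0015 for the unfolded protein response, -0.020 to 0.22 for epidermal differentiation, -0.028 to 0.014 for glutathione synthesis, -0.025 to 0.066 for glandular endocervix, -0.032 to 0.032 for platinum transporters and -0.031 to 0.035 for histones. In data simulated at this depth, 67.3% of 1.2-fold changes were recovered in genes at 10 CPM or more and 55.2% over all genes; other depths were not simulated.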

Other observations

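The test of H2AC19 and the shares and other splits of the 7-mer AATCCAA were chosen after the result was seen; the split of the ATF4 list was chosen once the 7-mer was known but before its own result was seen, and the other tests before their results were seen.

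Several of the largest relative rises were in genes at low levels, chosen here after their values were seen. CEMIP, whose product degrades hyaluronan, rose from 0.585 ± 0.0838 to 2.38 ± 0.689 CPM (SD, n = 3; 4.01-fold, edgeR adjusted p = 2.44e-04). RNF182, a ubiquitin ligase gene, rose from 1.55 ± 0.218 to 3.29 ± 0.0794 CPM (log2 1.08, adjusted p = 0.00202). Both calls held without any 1 library. The semaphorin gene SEMA6D (1.51), REEP1 (1.25), which shapes the endoplasmic reticulum, the complement regulator gene CFI (1.15), the circadian transcription factor gene NPAS2 (1.11) and TCF7L1 (1.02) also rose, and FILIP1L (-1.20) fell. Those 6 calls ended without single libraries: SEMA6D (shcontrol 1 or 2, shVPS13C 1 or 2, adjusted p up to 0.112), REEP1 (shcontrol 1 or 2, shVPS13C 2 or 3, 0.0729), CFI (shcontrol 1 or 3, shVPS13C 1 or 2, 0.184), NPAS2 (shcontrol 2, shVPS13C 1 or 2, 0.088), TCF7L1 (any but shcontrol 3, 0.202) and FILIP1L (shcontrol 2 or 3, shVPS13C 1 or 3, 0.106). LGALS9C (1.66) and TBC1D3C (1.40), members of families of near-identical genes, passed 2-fold too. So did MUC20 (1.36), TICAM2 (-1.13) and the readthrough gene ERV3-1-ZNF117 (-1.10). Stretches shared with other genes were not counted for any of them. These calls ended without single libraries too: LGALS9C (any but shcontrol 3, adjusted p up to 0.15), TBC1D3C (shcontrol 2 or shVPS13C 1, 0.12), MUC20 (any library, 0.141), TICAM2 (shcontrol 2, any shVPS13C, 0.329; log2 -0.50) and ERV3-1-ZNF117 (shcontrol 1, shVPS13C 1 or 2, 0.107). DESeq2 and robust quasi-likelihood also ended the calls of TBC1D3C (adjusted p = 0.288 and 0.151) and TICAM2 (0.331 and 0.368), and limma-voom that of TICAM2 (0.078).

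The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 570 changed genes and the highest of the others 1, so 1 of the 10 splits reached 570. For lists the real split gave 9 and the highest other 7, so 1 of 10 reached 9, and for transcripts it gave 0 and the highest other 0, so 10 of 10 reached it.

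Among genes lower in shVPS13C, the 7-mer AATCCAA was in the 3' UTR of 85 of 276 searched (30.8%). Length, GC content and expression of these genes predict 12.7%. It was in 28 of 288 higher genes (9.72%) and 1336 of 11803 not called (11.3%). AATCCAA was picked as the most negative 7-mer from the same values, so these shares are no separate evidence. The scan argues against any single 7-mer in 3' UTRs behind most of the falls. The largest excess of any of 15947 7-mers was 18.2 percentage points (SE 2.78). Matches of other lengths, shifted ones or those outside 3' UTRs were not added to it, so the scan cannot bound seed matches as a whole. Seed matches behind part of the falls stay open as a hypothesis, consistent with a t of -7.90 for that 7-mer, against -4.65 as the limit of 100 permutations and 4.23 as the most positive t; the next 7-mers, ATCCAAA and AAATCCA, are shifted copies of it (-5.17 and -5.04). The permutation limit is lax, because other splits of the libraries reached 5.50 in size against 8.02 for the real one (both from differences of mean log2 CPM, where the -7.90 is from the edgeR fold changes), and presence of the 7-mer in VPS13C says little, as 54.2% of 7-mers scanned are in a VPS13C transcript. The labels give no hairpin sequence, so an effect of VPS13C loss on the same genes stays open beside it, untested; carriers include IMPA2, TNIP1, TRIB3, ACSL4, SERPINH1, DSG2, BTG2 and HK1, which fell, and GJA5 and GUCY1A2, which rose.

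The lower ATF4 and integrated stress response list was tested against 3 technical explanations. A trend with GC content or transcript length is argued against, since the median over 28 members was -0.10 before and -0.11 (SE 0.041) after it was removed. A single library as the source is also argued against: the median nearest to 0 with 1 library left out was -0.068, with a camera adjusted p of at most 3.47e-06 at the preset correlation (adjusted p = 0.119 with an estimated correlation and all libraries). Seed matches cannot be told apart from a shift of the whole list, because the members without the 7-mer had a median of -0.051 (SE 0.038), although 7 of the 9 members that fell lack it. A biological difference between the groups stays open, untested.

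The fall of H2AC19 may come from reads shared with H2AC18. The counts of both genes summed had a log2 fold change of 0.057 (SE 0.041, edgeR adjusted p = 0.484), at 187 ± 8.17 CPM in shcontrol and 195 ± 5.60 in shVPS13C (SD, n = 3). Reads that fit both copies could be assigned to one or the other, since 97.1% of the 50-base stretches of H2AC19 are also in H2AC18. No biological explanation was tested.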
